A study of Homo sapiens with 21 samples.

How the data were processed

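Total RNA from punch biopsies of human skin was preserved in a stabilising solution, extracted, and used when its integrity number was at least 7, per the labels' protocols. It was amplified, labelled with biotin and hybridised to Illumina HumanHT-12 v4 bead arrays, which read the brightness of many beads per probe, per the labels' protocols. The submitters' processing notes name limma, with no version. The background correction, the normalization between arrays and the filter that left 29563 probes are not given in the sources used here. The values used were the authors' deposited log2 expression values, 1 per probe and array. The log base was inferred from the values, whose highest, read as a power of 2, lies within the range of a 16-bit scanner. Genes were not centred. That higher values mean brighter probes was inferred from the values. Array medians lay between 4.6 and 4.65. A further deposited table of scanner signals and detection p-values had 42 columns whose names match no sample, and none was used here.

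Groups came from the disease state in the labels: 10 HS and 11 Normal arrays. Slides were numbered 1 to 8 from the array labels. The comparison was HS minus Normal. It was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, group as the only term, two-sided), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. The plan made before the data were examined was to normalize the scanner signals with neqc and to keep probes by detection p. The scanner columns could not be given to samples, so the deposited values, planned as an alternative, became the values fitted, with probes kept where the value was over 5 on at least 10 arrays. This floor was set after the values were seen, near the upper edge of the dense band of dim probes. It left 11603 probes. The filter is not blind to group: a gene dim in 1 group is tested only where enough arrays of the other are bright. Shares of tested list members that rose or fell can therefore exceed the shares over all members. A gene over the floor in no array of a group has only a bound there, and its fold is given as at least that between the mean log2 values of the bright and the dim group, each dim array taken at the higher of the floor and its own value. Genes that did not reach the floor were read from a fit of all probes, with adjustment over all of them. For arrays, their number limits the precision.

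Probes were named through the platform's annotation: 22990 had 1 gene symbol, 3 had several and 6570 had none listed, and 0 symbols needed updating. A gene was read from its tested probe with the highest mean over the 21 arrays, which gave 8376 genes, and no gene was named from a probe with several symbols. Further tested probes were checked for all genes that the naming rule below picked, including some not named in the results. Only SDHC had a probe of opposite sign, and the probes of CXCL12, FCGR2B, IL10RB, PTTG1, RPS6 and VCAM1 differed in whether they passed. The 62 probes of Y-linked genes and XIST were left out throughout. The 37 gene lists were written before the data were examined, from textbook knowledge of pathways, skin cell types and other cell types a biopsy can hold. They hold 722 genes, of which 639 were on the table and 382 were tested, 13 were in more than 1 list (4 of these tested), and 36 lists had at least 2 tested members. Each list was tested with camera (preset correlation 0.01, which asks whether members shift more than other genes), with camera and an estimated correlation, and with fry, which asks whether members move on balance in 1 direction. Benjamini-Hochberg adjustment ran over the 36 lists. A list's median is over its tested genes, and its score on an array is the mean over those genes of the value minus the Normal mean. A further list of 20 general keratinocyte genes, 16 of them tested and 0 of these in another list, was written after the list results were seen and served only the tests of tissue composition.

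Genes were named by a rule fixed before the data were examined: the 12 largest rises and the 12 largest falls among genes past the threshold, up to 4 members past the threshold and up to 2 not past it for each list, taken by size of difference, and S100A7, S100A7A, DEFB4A, DCD, IFNG, IL17A, IL1B, IL6, TNF, CXCL13, MMP1, NCSTN, PSENEN and a gene that is not reported here. How many examples each list shows in the text was set after the values were seen. Near-identical gene copies are named as uncertain. Differences are given ± SE unless SD is written.

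The fits were tested on simulated data with each probe's Normal mean and its SD in each group. Of 200 changed probes among 11603, the fit recovered 30 of 50 at 1.5-fold, 40 of 50 at 2-fold and 50 of 50 at both 4-fold and 16-fold, with 0 in the wrong direction and 15 unchanged probes called beside them. With no probe changed it called 0. Of simulated lists with 12 members over 8376 genes, camera called 80 of 80 shifted lists and 2 of 640 unshifted lists. The simulated probes were drawn independently of each other. The estimated correlations within the real antimicrobial, type I and interferon-gamma lists were 0.40, 0.63 and 0.70. The simulation therefore does not show how often camera with the preset correlation errs on such lists.

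Alternatives fixed before the data were examined were no filter, eBayes without trend or with robust variances, array weights, slide as a fixed or random block, only the slides with both groups, each such slide alone, leaving out each slide or each array, the replicate number as a block, camera with an estimated correlation, fry, and the mean of a gene's probes or each other probe. Added after seeing the data were a floor of 5.5, a floor of 5 on at least 3 arrays, quantile normalization, centring of arrays, 1 array weight per group, and leaving out the HS arrays with a median correlation under 0.8 to the Normal arrays. That last choice takes out the HS arrays least like Normal. Smaller differences and lost calls are therefore partly built into it. It is no independent check of a call, also where a difference grows. Relations between list scores were tested over the 10 HS arrays by permutation. The scanner signals, alternatives that need them, and sequence or genome coordinates were not used here.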

Results

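Messenger RNA was measured with Illumina HumanHT-12 v4 bead arrays in 21 human skin biopsies. The 10 HS samples came from skin with hidradenitis suppurativa (HS), a chronic inflammatory disease that centres on hair follicles in skin folds. The 11 Normal samples were skin from abdominoplasty, the surgical removal of abdominal skin. Nothing in the labels says that the samples came from separate donors, so the p-values measure the spread between these samples, which may be technical. The values were the authors' deposited log2 values, with a median per array of 4.6 to 4.65, and 11032 to 11788 probes per array lay over a log2 value of 5. The number of arrays limits the precision of each difference. Across probes, pairs of Normal arrays correlated with a median r of 0.957 (0.929 to 0.981), pairs of HS arrays with 0.859 (0.629 to 0.968), and HS with Normal arrays with 0.862 (probes are not independent replicates). The median SD of a probe was 0.233 in Normal and 0.408 in HS, and 90.6% of tested probes had the higher SD in HS. Arrays HS 5, 7, 9 and 10 stood apart, with median correlations to the Normal arrays of 0.761, 0.783, 0.727 and 0.712. The 21 arrays lay on 8 slides, of which slides 2, 3, 4 and 5 held both groups (3 Normal and 2 HS arrays, 3 and 1, 2 and 1, and 1 and 1). Values with slide as a block therefore rest on 14 arrays for the comparison of the groups. Their HS arrays are HS 1, 2, 4, 9 and 10, while HS 3, 5, 6, 7 and 8 lay on slides without a Normal array. A call that ended with slide as a block may reflect this change of biopsies or slide, and these were not told apart. Slides 6 and 7 hold only HS 3 and HS 5, so leaving out either slide is the same fit as leaving out its array. On a slide, Normal arrays lay at positions up to 5 and HS arrays from position 6 on, so position and group cannot be told apart.

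The comparison asked which genes differ between HS and Normal skin, and the series title singles out antimicrobial peptides and interferon pathways. The gene with the largest rise in HS (n = 10) over Normal (n = 11) was IGLL1, an immunoglobulin light chain-like gene, with a log2 difference of 5.48 ± 0.66 (SE, adjusted p = 2.08e-05, a 44.6-fold difference). S100A9 and S100A8, the subunits of the antimicrobial protein calprotectin, followed with 4.88 ± 0.60 and 4.88 ± 0.60 (adjusted p = 2.22e-05 for each). IGLL1 was higher in 10 of 10 HS arrays than in every Normal array, but its sequence is related to the immunoglobulin lambda constant genes, so which gene its probe read is uncertain. The largest falls were in KRT2, a keratin of the upper epidermis, at -4.29 ± 0.97 (adjusted p = 0.00295), and SERPINA12, a serpin made in skin and fat, at -3.65 ± 0.54 (adjusted p = 0.000151). The elastase inhibitor PI3 rose by 4.20 ± 0.91 (adjusted p = 0.00221). MZB1, TENT5C, CD79A, JCHAIN and PIM2, genes of antibody-making cells, rose by 3.53, 3.37, 3.12, 2.91 and 2.77. The matrix-degrading enzymes MMP3 and MMP9 rose by 3.12 and 2.71, and thymidine phosphorylase (TYMP) by 2.98 ± 0.39 (adjusted p = 4.11e-05). Among the falls were the cornified envelope genes LCE5A (-3.36), LCE2B (-3.15) and LCE2D (-2.93), the filaggrin relative FLG2 (-3.09), the adhesion genes CLDN1 (-2.96) and DSC1 (-2.94), and C5orf46 (-3.23). KRT77, a keratin of sweat ducts, at -3.33 ± 0.38 (adjusted p = 1.22e-05), the anti-inflammatory cytokine IL37 at -3.29 ± 0.50 and the keratinocyte chemokine CCL27 at -3.23 ± 0.58 fell as well. PI3, MZB1, CD79A, MMP3 and JCHAIN were over a log2 value of 5 in 3, 2, 5, 3 and 1 of 11 Normal arrays, and KRT77, LCE5A, IL37 and CCL27 in 4, 5, 5 and 5 of 10 HS arrays, so their lower levels lie near background. The calls of PI3 (adjusted p = 0.0750), MMP3 (0.0787) and DSC1 (0.0680) ended with slide as a block. Those of LCE2D (adjusted p = 0.178), DSC1 (0.350), FLG2 (0.197), LCE2B (0.160) and KRT2 (0.0536) ended without the 4 HS arrays that stood apart.

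Of 11603 tested probes, 3435 (29.6%) passed an adjusted p of 0.05 in limma, 1460 higher and 1975 lower in HS, and 796 of these also differed at least 2-fold (391 higher, 405 lower). By gene, 1136 of 8376 rose and 1401 fell. In 22 probes every HS array was above every Normal array and in 58 every one was below, where chance would give 0.0329 probes per direction. With slide as a fixed block, 1857 probes passed (768 higher) and 613 at least 2-fold, and 1668 of the 1857 were among the 3435. Within slide 2 no probe passed in limma (0, against 1947 at an unadjusted p under 0.05). Within slides 3 and 4, which hold 1 HS array each (HS 9, which stood apart, and HS 2), 3423 and 644 passed (2574 and 642 at least 2-fold). The spread there comes from Normal arrays alone, which varied less than HS arrays, so these counts are no firm test. Slide 5, with 1 array per group, allowed no test. Without HS 5, 7, 9 and 10, an alternative chosen after seeing the data, 1484 probes passed (596 higher, 307 at least 2-fold). These arrays were picked for their low correlation with the Normal arrays, so a lower count is partly built into that choice. Leaving out slides 2, 3 or 8 gave 2066, 1823 or 1674.

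**Figure D1:**
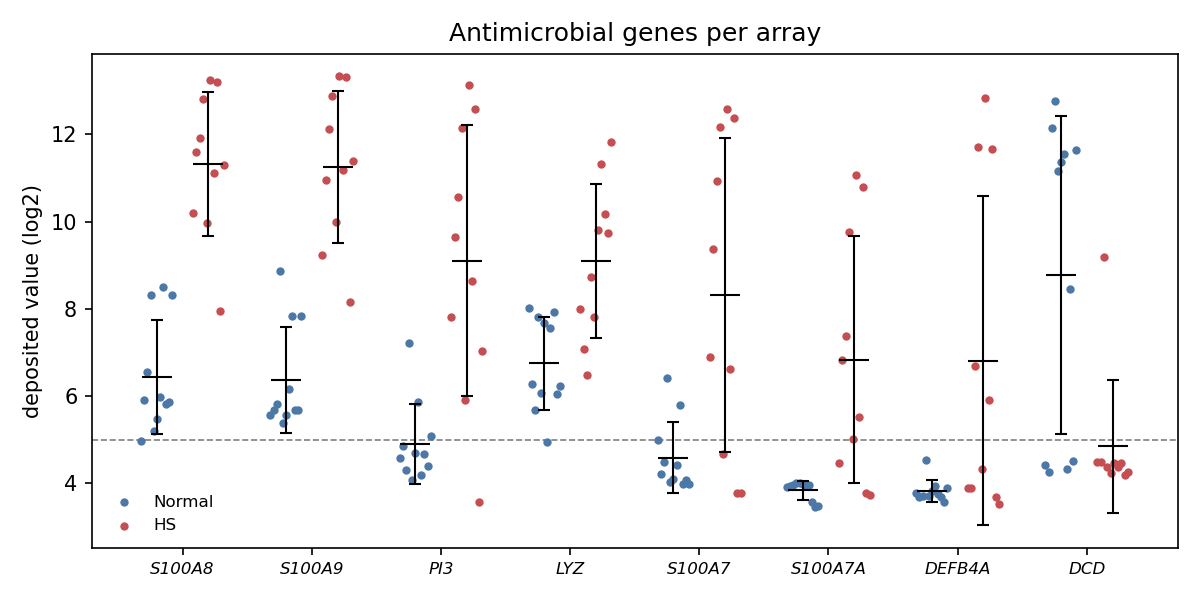
The y axis gives the deposited log2 value of 8 antimicrobial genes, 1 point per array (11 Normal, 10 HS), with bars for the mean ± SD of each group and a dashed line at 5, the floor used for testing. S100A8 and S100A9 are higher in 9 of 10 HS arrays than in every Normal array, while DEFB4A exceeds 5 in 5 HS arrays and DCD in 1 HS and 7 Normal arrays.

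Antimicrobial peptides and proteins are made by keratinocytes, glands and phagocytes. Of 12 tested members, 5 rose, 1 fell and 6 did not pass, and adjusted over the list alone 5 rose and 1 fell. Beside S100A8, S100A9 and PI3, lysozyme (LYZ) rose by 2.35 ± 0.59 (adjusted p = 0.00583). The member that fell, neutrophil elastase (ELANE), at -1.08 ± 0.23 (adjusted p = 0.00222), was over the floor in 1 HS and 9 Normal arrays and was named after its value was seen. The epithelial defensin DEFB1 did not pass, at -1.72 ± 0.84 (adjusted p = 0.121). In a fit of all probes, which also takes in genes near background, 8 of 24 members rose and 2 fell. There S100A7 (psoriasin) rose by 3.72 ± 1.0 (adjusted p = 0.0175), over the floor in 7 HS and 2 Normal arrays. Its relative S100A7A, over the floor in no Normal array, was at least 3.58-fold higher in HS (adjusted p = 0.0133). DEFB4A, a defensin with a near-identical gene copy and so uncertain, was over the floor in 5 HS and no Normal arrays and did not pass (at least 3.52-fold higher by its means, adjusted p = 0.0591). The sweat peptide gene DCD, over the floor in 1 HS and 7 Normal arrays, fell, at -3.93 ± 1.12 (adjusted p = 0.0239). The HS levels of ELANE and DCD lie near background, which limits how exact these differences are.

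As a list, the antimicrobial genes shifted up (median log2 difference 0.63, camera adjusted p = 0.0292, and adjusted p = 0.460 with an estimated correlation). The per-array mean of the list was above all Normal arrays in 4 of 10 HS arrays and below them in 1. The call ended with slide as a block (median 0.20, adjusted p = 0.286). Within slides 2 to 5 the medians were 0.81, -1.29, 0.34 and 0.95. It also ended without HS 3, 4, 6 or 8 (medians 0.59, 0.55, 0.41 and 0.37, adjusted p = 0.0662, 0.0637, 0.0555 and 0.0648). Without slide 4 or 8 the adjusted p was above 0.05 as well (0.0588 and 0.133). Leaving out slide 6, which holds only HS 3, is the same fit as leaving out HS 3 (0.0662). HS 5, 7, 9 and 10 were picked after the data were seen and had the lowest epidermal scores. A fit without them is thus no independent check, and the list median there was 1.59 (camera adjusted p = 1.25e-06). Over all 24 members, with no filter, it was 0.36 (adjusted p = 0.00432), with a floor of 5 on at least 3 arrays 0.96, with array weights 1.33, and without slide 8 0.25. Slide as a block leaves HS 3, 5, 6, 7 and 8 out of the comparison (S100A7 values 10.9, 4.67, 12.6, 6.63 and 12.4). It keeps HS 1, 2, 4, 9 and 10 (6.90, 9.37, 12.2, 3.78 and 3.79). The calls of PI3 (adjusted p = 0.0750), S100A7 (0.260), S100A7A (0.255) and DCD (0.0810) ended with slide as a block. Those of LYZ (adjusted p = 0.0556) and DCD (0.160) ended without the 4 HS arrays that stood apart. On the same samples the epidermal differentiation list had a median of -2.17 and the stress keratin list a median of 1.34. Neutrophil and macrophage markers had medians of 0.83 and 1.33 (adjusted p = 0.327 and 0.282 with an estimated correlation), and phagocytes also make LYZ, S100A8 and S100A9.

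Interferon-responsive genes were higher in HS. Of 23 tested type I interferon-stimulated genes, which limit virus growth in many cell types, 19 rose, 0 fell and 4 did not pass (adjusted over the list alone, 20 rose). EPSTI1 rose by 2.13 ± 0.41 (adjusted p = 0.000940), the exonuclease ISG20 by 2.01 ± 0.40, IFI27 by 1.84 ± 0.39 and the tethering protein gene BST2 by 1.65 ± 0.28 (adjusted p = 0.000441). IFIT3 did not pass at 0.68 ± 0.29 (adjusted p = 0.0836), or 0.44 without HS 7. Of 20 genes of the interferon-gamma response and antigen presentation, 18 rose and 2 did not pass (adjusted over the list alone, 19 rose). The chemokine gene CXCL10 rose by 2.32 ± 0.52 (adjusted p = 0.00290), the transcription factor gene IRF1 by 1.82 ± 0.31 and GBP1, of the guanylate-binding proteins, by 1.75 ± 0.39. GBP4, over the floor in no Normal array, was at least 2.57-fold higher (adjusted p = 0.000590). HLA-F did not pass at 0.49 ± 0.23 (adjusted p = 0.111). CXCL10 was over the floor in 3 of 11 Normal arrays. Of 4 tested interferon and receptor genes 3 rose (adjusted over the list alone, 3), among them the receptor subunits IFNAR2 (1.44) and IFNAR1 (0.78). IFNLR1 stood at -0.33 ± 0.22 (adjusted p = 0.255), or -0.16 without HS 10. IFNG itself was over the floor in 1 HS and 0 Normal arrays and did not pass (adjusted p = 0.101). The calls of IFNAR2 (adjusted p = 0.0662) and IFNAR1 (0.0512) ended without the 4 HS arrays that stood apart.

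The type I list had a median log2 difference of 1.06, camera adjusted p = 3.37e-10, and adjusted p = 0.279 with an estimated correlation. The interferon-gamma list had a median log2 difference of 1.15, camera adjusted p = 3.37e-10, and adjusted p = 0.279 with an estimated correlation. Their per-array means were above all Normal arrays in 7 and 8 of 10 HS arrays. With slide as a block the medians were 1.02 (adjusted p = 2.57e-09) and 1.09 (adjusted p = 9.97e-10). Within slides 2 to 5 they were 0.96, 1.55, 0.73 and 0.29 for type I and 1.19, 1.68, 1.13 and 0.72 for interferon-gamma. Without HS 5, 7, 9 and 10 they were 0.67 and 0.68. The interferon and receptor list had a median log2 difference of 0.59, camera adjusted p = 0.0423, and adjusted p = 0.279 with an estimated correlation. Its call ended with slide as a block (adjusted p = 0.113), without the 4 HS arrays (median 0.35, adjusted p = 0.0734), without slide 4, 7 or 8, and without HS 2, 5, 6 and 7 (medians 0.56 to 0.58, adjusted p = 0.0506 to 0.0603). On these samples 5 of 5 T cell markers and 8 of 10 monocyte and macrophage markers rose too, with list medians of 1.58 and 1.33 (adjusted p = 0.279 and 0.282 with an estimated correlation). With no filter 9 of 18 and 8 of 15 of these markers rose. The median for interferon and receptor genes was 0.61 with slide as a block and 0.53, 0.99, 0.20 and 0.35 within slides 2 to 5.

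**Figure D2:**
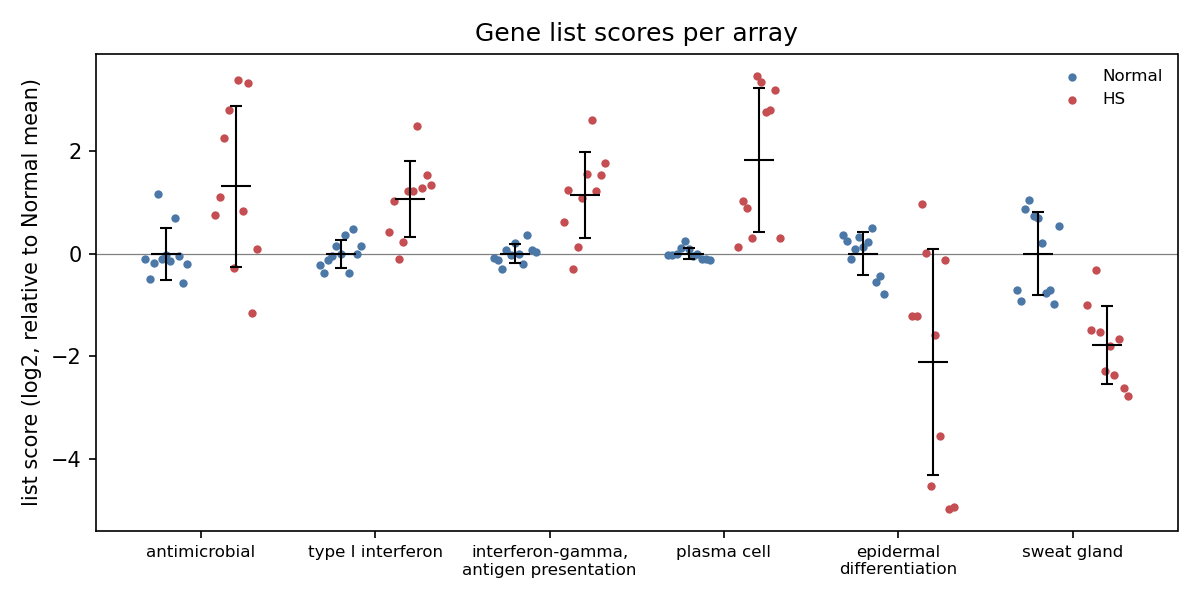
The y axis gives the list score, the mean over a list's tested genes of the log2 value minus the Normal mean, for 6 lists, with 1 point per array (11 Normal, 10 HS) and bars for the mean ± SD. The plasma cell scores are above all Normal arrays in 9 of 10 HS arrays and the sweat gland scores below all Normal arrays in 9, while the antimicrobial and epidermal scores of HS arrays spread to both sides of the Normal ones.

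Inflammatory genes rose in part. Of 16 tested IL-1, TNF and NF-kB genes, 8 rose and 8 did not pass (adjusted over the list alone, 8 rose). The neutrophil chemokine CXCL8 rose by 2.51 ± 0.68 (adjusted p = 0.00902), the antioxidant enzyme gene SOD2 by 2.12 ± 0.39, IL6 by 1.81 ± 0.48 (adjusted p = 0.00789) and IL1B by 1.62 ± 0.48 (adjusted p = 0.0162). OSM did not pass at 0.57 ± 0.26 (adjusted p = 0.101). TNF, over the floor in 4 HS and 2 Normal arrays, stood at 0.26 ± 0.22 (adjusted p = 0.499) in the fit of all probes, at 0.08 without HS 7 and at 0.16 without HS 1. CXCL8, IL6, IL1B, OSM and CCL20 were over the floor in 5, 3, 3, 3 and 4 Normal arrays. The IL-1 list had a median log2 difference of 0.73, camera adjusted p = 0.00233, and adjusted p = 0.327 with an estimated correlation. Its median was 1.25 with a floor of 5.5 and 0.45 without slide 8. Of 5 tested genes of the IL-17, IL-23 and IL-36 axis, 1 rose (adjusted over the list alone, 1), the RNase gene ZC3H12A at 1.28 ± 0.28 (adjusted p = 0.00241). Among the 16 genes of this axis on the table, 3 rose and 1 fell with no filter. CCL20 did not pass at 0.81 ± 0.40 (adjusted p = 0.122). The IL-17 list was not called (median 0.16, camera adjusted p = 0.306), and its median ran from -0.22 with slide as a block and -0.12 without slide 8 to 0.70 with a floor of 5.5, 0.75 with array weights and 1.10 without the 4 HS arrays. IL17A was over the floor in 0 arrays (adjusted p = 0.973). Genes of inflammasomes and their products rose in 4 of 5 (adjusted over the list alone, 4), among them IL18BP, a secreted inhibitor of IL-18 (1.35), and the pore protein gene GSDMD (1.33). PYCARD did not pass at 0.14 ± 0.25 (adjusted p = 0.691), with 0.03 to 0.28 when each array was left out in turn. The inflammasome list had a median log2 difference of 0.76, camera adjusted p = 0.00107, and adjusted p = 0.279 with an estimated correlation. Among its 13 genes on the table, 6 rose with no filter. On the same samples 5 of 6 neutrophil and 8 of 10 macrophage markers rose, with medians of 0.83 and 1.33 (adjusted p = 0.327 and 0.282 with an estimated correlation). With no filter 5 of 14 and 8 of 15 of these markers rose. The median for IL-1, TNF and NF-kB genes was 0.45 with slide as a block and 1.28, 0.01, 0.09 and 0.12 within slides 2 to 5. In the same order the medians were -0.22 and 0.01, -0.22, 0.99 and 0.32 for IL-17 axis genes, and 0.62 and 0.93, 0.40, 1.06 and 0.21 for inflammasome genes.

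Pattern recognition receptor genes rose in 4 of 6 (adjusted over the list alone, 5), with LY96 at 1.80 and CD14, both parts of endotoxin sensing, at 1.45. IRAK3 did not pass at 0.51 ± 0.22 (adjusted p = 0.0843). The pattern receptor list had a median log2 difference of 0.50, camera adjusted p = 0.00438, and adjusted p = 0.279 with an estimated correlation. Of 12 complement genes 7 rose, 2 fell and 3 did not pass (adjusted over the list alone, 8 and 3), with C1QB at 2.26 and CFB at 1.82. SERPING1 did not pass at 0.57 ± 0.26 (adjusted p = 0.0953). The complement list had a median log2 difference of 0.82, camera adjusted p = 0.0285, and adjusted p = 0.327 with an estimated correlation. Over all 19 complement genes, with no filter, the median was 0.50. The complement call ended without the 4 HS arrays (median 0.34, adjusted p = 0.0802). JAK-STAT genes, which relay cytokine signals, rose in 4 of 11 (adjusted over the list alone, 4), among them STAT4 (1.13) and the feedback inhibitor SOCS3 (1.12). PIM1 did not pass at -0.38 ± 0.23 (adjusted p = 0.225). STAT4, SOCS3 and IRAK3 were over the floor in 5, 2 and 5 Normal arrays. That list had a median log2 difference of 0.18, camera adjusted p = 0.0453, and adjusted p = 0.279 with an estimated correlation. Its call ended with slide as a block (0.0707), without slide 1, 2, 3, 4, 7 or 8, with a floor of 5.5, with array weights, per array or per group, and without Normal 3, 4, 5, 7 and 8 or HS 2, 5 and 7 (medians 0.15 to 0.26, adjusted p = 0.0506 to 0.0748). Without HS 10 the median was 0.11, without slide 2 it was 0.047 (adjusted p = 0.0823), and without slide 4 0.31. Without the 4 HS arrays the JAK-STAT median was -0.01 (adjusted p = 0.155). The median for pattern recognition receptor genes was 0.59 with slide as a block and 0.91, 0.61, 1.01 and 0.51 within slides 2 to 5. In the same order the medians were 0.99 and 0.93, 1.63, 0.04 and 0.51 for complement genes, and 0.32 and 0.07, 0.38, 0.20 and 0.03 for JAK-STAT genes. The calls of CXCL8 (adjusted p = 0.0849), IL1B (0.179), ZC3H12A (0.0577) and SOCS3 (0.108) ended with slide as a block. Those of IL1B (adjusted p = 0.137), IL6 (0.0563), SOCS3 (0.0546) and CD14 (0.130) ended without the 4 HS arrays that stood apart.

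Markers of lymphocytes were higher in HS. Plasma cell genes rose in 7 of 8 (adjusted over the list alone, 7), and in 12 of 15 with no filter. SDC1 did not pass at -0.58 ± 0.37 (adjusted p = 0.231), or -0.27 without HS 10. Keratinocytes also make SDC1. The plasma cell list had a median log2 difference of 2.07, camera adjusted p = 0.000320, and adjusted p = 0.279 with an estimated correlation. Both tested B cell genes, CD79A and CD79B (1.43), parts of the B cell receptor, rose (2 of 2, adjusted over the list alone, 2). The B cell list had a median log2 difference of 2.27, camera adjusted p = 0.0292, and adjusted p = 0.279 with an estimated correlation. Over all 13 members, with no filter, 3 rose and the median was 0.48, and with a floor of 5 on at least 3 arrays it was 0.63. The B cell call ended with slide as a block (0.0707) and without slide 4 or 8 (0.0556 and 0.0622). T cell genes rose in 5 of 5 (adjusted over the list alone, 5), with IL7R at 1.85 and CD3D at 1.77. The T cell list had a median log2 difference of 1.58, camera adjusted p = 0.000320, and adjusted p = 0.279 with an estimated correlation. With no filter 9 of 18 T cell genes rose, and the median was 0.50. Cytotoxic and NK cell genes rose in 4 of 4 (adjusted over the list alone, 4), with KLRB1 at 1.86 and the granzyme GZMA at 1.77. With no filter 8 of 12 cytotoxic and NK cell genes rose. The cytotoxic list had a median log2 difference of 1.53, camera adjusted p = 0.00107, and adjusted p = 0.279 with an estimated correlation. Genes of lymphoid organisation rose in 5 of 8 and fell in 1 (adjusted over the list alone, 6 and 1), with LTB at 2.09 and CCL5 at 1.83. CCL18 did not pass at 0.90 ± 0.42 (adjusted p = 0.107), or 0.57 without HS 10. The lymphoid organisation list had a median log2 difference of 1.35, camera adjusted p = 0.00520, and adjusted p = 0.279 with an estimated correlation. The member that fell stood at -1.01. GZMA and CCL18 were over the floor in 4 Normal arrays each. Without HS 5, 7, 9 and 10 the medians of the T cell, cytotoxic and lymphoid organisation lists were 0.97, 0.82 and 0.71. CXCL13, a B cell chemokine over the floor in 6 HS and no Normal arrays, was at least 4.51-fold higher in the fit of all probes (adjusted p = 0.00795). The median for plasma cell genes was 1.46 with slide as a block and 0.33, 3.79, 1.06 and 0.29 within slides 2 to 5. In the same order the medians were 1.35 and 0.08, 3.95, 1.71 and -0.02 for B cell genes, 1.34 and 1.47, 1.51, 1.12 and 1.18 for T cell genes, 1.26 and 1.09, 2.49, 0.66 and 0.80 for cytotoxic and NK cell genes, and 1.25 and 1.45, 1.80, 0.51 and 0.63 for lymphoid organisation genes.

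Neutrophil genes rose in 5 of 6 (adjusted over the list alone, 5), with the receptor genes CSF3R at 1.86 and FPR1 at 1.40. AQP9 did not pass at -0.80 ± 0.48 (adjusted p = 0.215), or -0.39 without HS 9. CSF3R and FPR1 were over the floor in 4 and 3 Normal arrays, and the Langerhans cell gene CD207 in 5 HS arrays. The neutrophil list had a median log2 difference of 0.83, camera adjusted p = 0.0129, and adjusted p = 0.327 with an estimated correlation. With no filter 5 of its 14 genes rose, and the median over them was 0.53. Monocyte and macrophage genes rose in 8 of 10 (adjusted over the list alone, 9), with CD68 at 1.73 and CD163 at 1.53. CSF1R did not pass at 0.65 ± 0.28 (adjusted p = 0.0845). The macrophage list had a median log2 difference of 1.33, camera adjusted p = 0.000314, and adjusted p = 0.282 with an estimated correlation. Its median was 0.56 without the 4 HS arrays that stood apart. Of 6 dendritic and Langerhans cell genes 1 rose and 2 fell (adjusted over the list alone, 1 and 2). The falls were FCER1A, part of the IgE receptor, at -1.68 ± 0.45 (adjusted p = 0.00924), and the Langerhans cell lectin CD207 at -1.12 ± 0.27 (adjusted p = 0.00439). The median of that list was 0.29 and its mean -0.13, and it was not called (camera upward, adjusted p = 0.928, fry downward). Over all 13 members, with no filter, the median was 0.06, and without HS 9 it was 0.16 over the tested members. LAMP3 stood at 0.66 ± 0.31 (adjusted p = 0.113), or 0.44 without HS 7, and its dimmer probe at 0.24 (adjusted p = 0.165). The rise, named after its value was seen, was in the Fc receptor gene FCGR2B at 0.76 (adjusted p = 0.0465), but its dimmer probe did not pass, at 0.07 (adjusted p = 0.750). The dimmest CD163 probe passed at 0.95 (adjusted p = 0.0460). Mast cell genes rose in 1 of 5 (adjusted over the list alone, 1), the carboxypeptidase CPA3 at 1.13 ± 0.40 (adjusted p = 0.0371). The CPA3 call ended without any 1 of Normal 1, 2, 3, 10 and 11 and HS 5, 6, 7, 8 and 9 (0.91 to 1.15, adjusted p = 0.0507 to 0.0684), with no filter, with 1 weight per group, and without slide 2, 3, 7 or 8. HDC did not pass at 0.56 ± 0.25 (adjusted p = 0.0936), and the mast cell list was not called (median 0.50, camera adjusted p = 0.234). The median for neutrophil genes was 0.84 with slide as a block and 1.42, 1.12, 0.19 and 0.20 within slides 2 to 5. In the same order the medians were 1.49 and 1.97, 1.93, -0.03 and 1.12 for monocyte and macrophage genes, 0.36 and -0.11, 1.01, -0.58 and 0.89 for dendritic cell genes, and 0.29 and -0.10, 1.18, -0.28 and 0.64 for mast cell genes. The calls of CD79B (adjusted p = 0.0880), CSF3R (0.0589), FPR1 (0.108), CD163 (0.112), FCER1A (0.139), CD207 (0.0633), CXCL13 (0.0955) and CPA3 (0.238) ended with slide as a block. Those of FPR1 (adjusted p = 0.0845), CD163 (0.314), FCER1A (0.111), CD207 (0.0992), CXCL13 (0.115) and CPA3 (0.12) ended without the 4 HS arrays that stood apart.

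Genes of the epidermal barrier fell in part. Of 31 tested epidermal differentiation genes 0 rose, 19 fell and 12 did not pass (adjusted over the list alone, 26 fell), led by KRT2, LCE5A, LCE2B and FLG2. LORICRIN, a cornified envelope protein gene, did not pass at -2.82 ± 1.16 (adjusted p = 0.0680). The epidermal list had a median log2 difference of -2.17, camera adjusted p = 2.44e-08, and adjusted p = 0.327 with an estimated correlation. Its per-array mean was below all Normal arrays in 7 of 10 HS arrays and above them in 1. With slide as a block the median was -2.41 (adjusted p = 1.16e-09), and within slides 2 to 5 it was -2.50, -5.35, -0.66 and -0.27. Without HS 5, 7, 9 and 10 it was -0.51 (adjusted p = 0.0306). The scores of those 4 arrays were -4.52, -3.56, -4.97 and -4.93, and the other 6 lay between -1.59 and 0.97. Stress keratins and activated keratinocyte genes, switched on in wounded or inflamed epidermis, rose in 3 of 13 with 10 not passing (adjusted over the list alone, 1). KRT6C did not pass at 2.69 ± 1.12 (adjusted p = 0.0728). That list had a median log2 difference of 1.34, camera adjusted p = 0.0285, and adjusted p = 0.569 with an estimated correlation. The stress keratins were not called by fry (adjusted p = 0.209), and with no filter 6 of 23 genes of that list rose. The stress keratin call ended with slide as a block (median 0.15, adjusted p = 0.759, and 0.83, -2.43, 1.22 and -0.12 within slides 2 to 5), without slide 4, 6 or 8, and without HS 3, 4, 6 and 8 (medians 0.95 to 1.17, adjusted p = 0.0781 to 0.0968). Its median was 0.40 without slide 8, 2.27 with array weights and 2.57 without HS 5, 7, 9 and 10, the arrays with the lowest epidermal scores. KRT6C was over the floor in 5 Normal arrays.

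The stress keratin members SPRR2F (2.43 ± 0.91, adjusted p = 0.0487) and SERPINB3 (2.40 ± 0.88, adjusted p = 0.0447) passed by little. The SPRR2F call ended without any 1 of Normal 1, 2, 3, 5, 6, 7, 8, 9, 10 and 11 and HS 2, 3, 4, 6 and 8 (log2 differences 1.98 to 2.49, adjusted p = 0.0586 to 0.0945). The SERPINB3 call ended without any 1 of Normal 1, 2, 5, 6, 7, 9, 10 and 11 and HS 3, 4, 6 and 8 (1.98 to 2.48, adjusted p = 0.05 to 0.0865). With slide as a block their adjusted p was 0.402 and 0.470. Of 9 eccrine and apocrine gland genes, which mark sweat glands, 8 fell and 1 did not pass (adjusted over the list alone, 8 fell), with the secretoglobin SCGB1D2 at -2.71 ± 0.61 (adjusted p = 0.00302). SCGB1D2 was over the floor in 1 HS and 9 Normal arrays, so its HS level lies near background. CA2 did not pass at -0.72 ± 0.68 (adjusted p = 0.428), or -0.45, -0.38 and -0.41 without HS 5, 9 and 10 in turn. Among 21 gland genes on the table, 13 fell with no filter. The gland list had a median log2 difference of -1.60, camera adjusted p = 0.000219, and adjusted p = 0.279 with an estimated correlation. Its score lay below all Normal arrays in 9 of 10 HS arrays, and with slide as a block it had a median of -1.74 (within slides 2 to 5, -2.38, -2.38, -0.35 and -1.90). Hair follicle genes fell in 3 of 5 (adjusted over the list alone, 3), among them the root sheath keratins KRT73 (-2.08) and KRT72 (-1.48). KRT15 did not pass at -1.52 ± 0.81 (adjusted p = 0.156). The hair follicle list had a median log2 difference of -1.48, camera adjusted p = 0.00520, and adjusted p = 0.279 with an estimated correlation. KRT73 and KRT72 were over the floor in 5 and 2 HS arrays. With no filter 4 of 24 hair follicle genes fell, and the median was -0.38, and with a floor of 5 on at least 3 arrays it was -0.79. The hair follicle call ended without the 4 HS arrays (median -0.74, adjusted p = 0.0877). The median for hair follicle genes was -1.36 with slide as a block and -1.31, -1.84, -0.25 and -1.59 within slides 2 to 5. In this order the medians were 0.30 and 0.88, 0.92, -0.79 and -0.53 for sebaceous genes. The labels give no body site for the HS samples. Of 6 sebaceous gland genes ACSBG1 fell (-1.48 ± 0.42, adjusted p = 0.0120, 1 of 6, adjusted over the list alone, 1). It was over the floor in 5 HS arrays. The sebaceous list was not called (median 0.31, mean -0.01, camera upward, adjusted p = 0.725). Its median turned to -0.12 over all 18 members with no filter, and to -0.12 with a floor of 5 on at least 3 arrays. The call of DSC1 (adjusted p = 0.0680) ended with slide as a block. Those of KRT2 (adjusted p = 0.0536), DSC1 (0.350), FLG2 (0.197) and ACSBG1 (0.221) ended without the 4 HS arrays that stood apart.

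**Figure D3:**
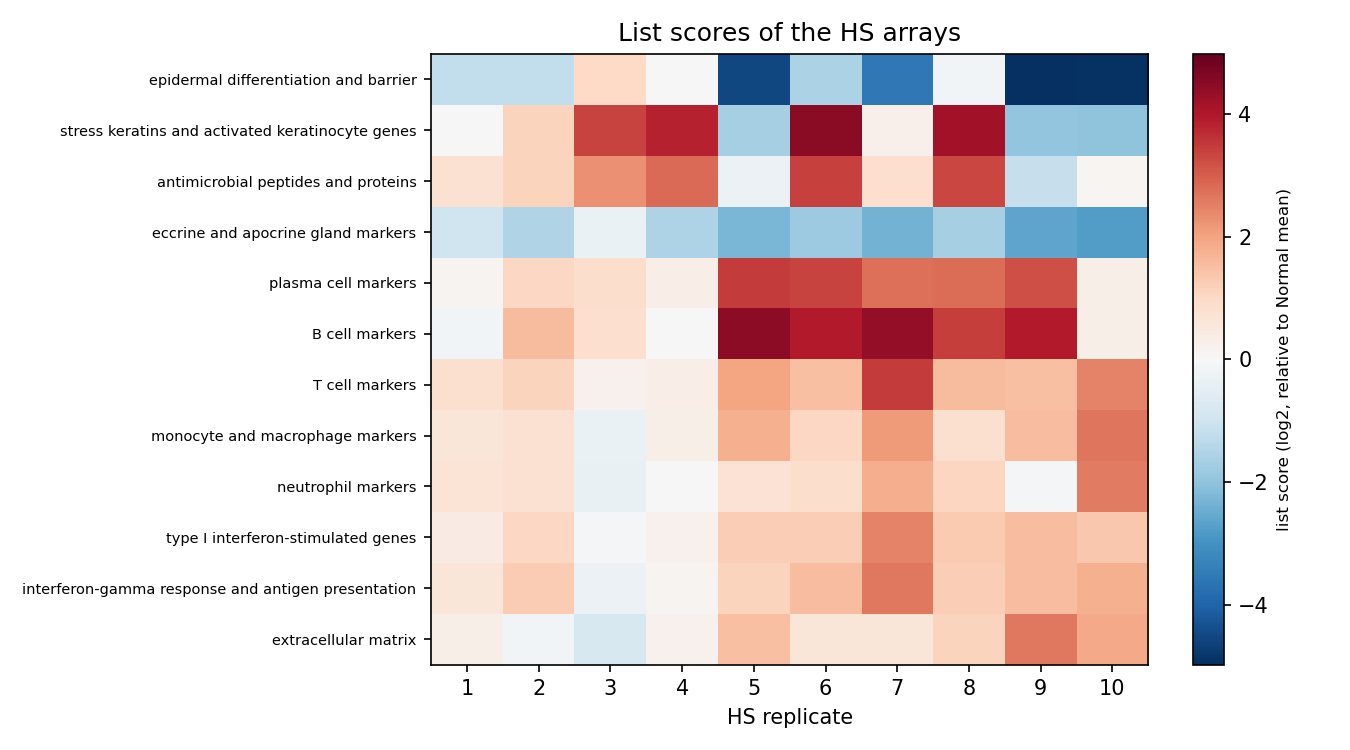
Colour gives the list score (log2, relative to the Normal mean) of 12 gene lists, down the y axis, in each of the 10 HS arrays, along the x axis. HS 5, 7, 9 and 10 have epidermal scores of -4.52, -3.56, -4.97 and -4.93, and HS 3, 4, 6 and 8 have stress keratin scores of 3.35, 3.81, 4.49 and 4.20.

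Matrix and vessel genes rose in part. Of 23 extracellular matrix genes 7 rose and 16 did not pass (adjusted over the list alone, 9 rose). The collagen genes COL4A1 and COL5A2 rose by 2.17 ± 0.39 (adjusted p = 0.000566) and 1.72. THBS1 did not pass at 1.18 ± 0.46 (adjusted p = 0.0591). The matrix list had a median log2 difference of 0.85, camera adjusted p = 0.000885, and adjusted p = 0.460 with an estimated correlation. It was not called by fry (adjusted p = 0.0729), and the call ended without the 4 HS arrays (median 0.15, adjusted p = 0.154). Matrix metalloproteinases and their inhibitors rose in 5 of 9 and fell in 1 (adjusted over the list alone, 5 and 1). MMP7 did not pass at -0.96 ± 0.46 (adjusted p = 0.113). The metalloproteinase list had a median log2 difference of 0.87, camera adjusted p = 0.0334, and adjusted p = 0.352 with an estimated correlation. The metalloproteinase call ended without Normal 2 (median 0.86, adjusted p = 0.0630), without slide 2 (0.0690), without the 4 HS arrays (0.0854) and with a floor of 5.5 (median 0.13, adjusted p = 0.394). The collagenase gene MMP1, over the floor in 5 HS and no Normal arrays, was at least 1.88-fold higher in the fit of all probes (adjusted p = 0.0348). MMP1 no longer passed without slide 8 (adjusted p = 0.239). Its call ended without any 1 of Normal 1, 2, 3, 4, 5, 6, 7 and 8 and HS 6, 7, 8 and 10 (adjusted p = 0.0515 to 0.0699), and with slide as a block (adjusted p = 0.214). Endothelial genes rose in 8 of 13 (adjusted over the list alone, 9 rose and 1 fell), with VCAM1 and PECAM1, adhesion molecules of vessel walls, at 1.74 and 1.5. A dimmer VCAM1 probe did not pass, at 0.59 (adjusted p = 0.0766). LYVE1 did not pass at -0.94 ± 0.41 (adjusted p = 0.0879). The endothelial list had a median log2 difference of 0.77, camera adjusted p = 0.000877, and adjusted p = 0.327 with an estimated correlation. Without the 4 HS arrays its median was 0.24. The median for matrix genes was 1.26 with slide as a block and 1.20, 3.03, -0.30 and 0.67 within slides 2 to 5. In the same order the medians were 0.84 and 1.5, 1.08, -0.07 and 0.58 for metalloproteinases and inhibitors, and 1.02 and 1.40, 1.89, -0.19 and 0.30 for endothelial genes.

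Cell cycle genes rose in 4 of 15 with 11 not passing (adjusted over the list alone, 2), among them the cyclins CCNA2 (0.70) and CCNB2 (0.70). TYMS stood at 0.64 ± 0.27 (adjusted p = 0.0740). The cell cycle list had a median log2 difference of 0.40, camera adjusted p = 0.00438, and adjusted p = 0.467 with an estimated correlation. That call ended with slide as a block (0.1), without slide 2 (median 0.21, adjusted p = 0.0806) and with fry (adjusted p = 0.0756). Melanocyte genes fell in 2 of 7 (adjusted over the list alone, 2), SOX10 at -0.57 ± 0.16 (adjusted p = 0.0102) and MITF at -0.52 ± 0.13 (adjusted p = 0.00587). SOX10 was over the floor in 1 HS and 9 Normal arrays and MITF in 5 HS arrays. TYRP1 did not pass at -1.01 ± 0.71 (adjusted p = 0.286). The melanocyte list had a median log2 difference of -0.59, camera adjusted p = 0.0453, and adjusted p = 0.467 with an estimated correlation. The melanocyte call ended without Normal 2, 3, 7, 8 and 10 or HS 2, 5, 6, 7, 9 and 10 (medians -0.61 to -0.52, adjusted p = 0.0513 to 0.0914), without slide 2, 3, 4, 7 or 8, with a floor of 5.5, with array weights and with quantile normalization. With a floor of 5.5 the melanocyte median was -0.90. Without the 4 HS arrays it was 0.17 (adjusted p = 0.956). The median for cell cycle genes was 0.28 with slide as a block and 1.22, -0.39, -0.50 and -0.24 within slides 2 to 5. In the same order the medians were -0.74 and -0.87, -1.98, 0.08 and 0.11 for melanocyte genes. The calls of CCNA2 (adjusted p = 0.111), CCNB2 (0.208) and MMP3 (0.0787) ended with slide as a block. Those of COL5A2 (adjusted p = 0.149), VCAM1 (0.0539) and SOX10 (0.170) ended without the 4 HS arrays that stood apart.

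Of 16 Notch pathway and gamma-secretase genes, which include genes mutated in some families with HS, 1 rose, 3 fell and 12 did not pass (adjusted over the list alone, 4 rose and 6 fell). The gamma-secretase subunit gene NCSTN rose by 0.33 ± 0.10 (adjusted p = 0.0179), and PSENEN did not pass at 0.23 ± 0.09 (adjusted p = 0.0725). The ligand gene JAG2 fell, at -0.68 ± 0.20 (adjusted p = 0.0141), as did the target gene HES1, at -0.65 ± 0.23 (adjusted p = 0.0359). The HES1 call ended without any 1 of Normal 2, 3, 4, 7 and 11 and HS 5, 6, 7, 9 and 10 (-0.65 to -0.57, adjusted p = 0.0501 to 0.0693), with no filter, with array weights, and without slide 2, 3, 7 or 8. HEYL stood at 0.62 ± 0.24 (adjusted p = 0.0555). That list was not called, with a median of -0.09, an upward camera test (adjusted p = 0.981) and a downward fry test. Ribosomal protein genes, a reference for scaling, fell in 9 of 20 and rose in 1 (adjusted over the list alone, 9 and 1), with RPL7 at -0.64 and RPL37 at -0.59. RPS6 did not pass at -0.23 ± 0.12 (adjusted p = 0.151), but its dimmer probe did, at -0.33 (adjusted p = 0.0184). The ribosomal list had a median log2 difference of -0.19, camera adjusted p = 0.00400, and adjusted p = 0.327 with an estimated correlation. The ribosomal call ended without the 4 HS arrays (0.0854). The median for ribosomal protein genes was -0.24 with slide as a block and -0.23, -0.41, -0.18 and -0.05 within slides 2 to 5. In this order the medians were -0.15 and -0.16, -0.15, 0.08 and 0.01 for Notch genes, and -0.06 and 0.07, -0.27, -0.15 and -0.01 for oxidative phosphorylation genes. Oxidative phosphorylation genes rose in 2 of 22 (adjusted over the list alone, 0), COX5A at 0.26 ± 0.09 (adjusted p = 0.0299) and COX8A at 0.26 ± 0.09 (adjusted p = 0.0335), and were not called (median -0.01, mean 0.00, camera upward, adjusted p = 0.531). The COX5A call ended without any 1 of Normal 2 and 9 and HS 6 and 7 (0.23 to 0.25, adjusted p = 0.0521 to 0.0602), and the COX8A call without any 1 of Normal 1, 2, 5 and 9 and HS 6, 7 and 10 (0.22 to 0.25, adjusted p = 0.0537 to 0.0655). Both also ended with no filter, with quantile normalization, and without slide 1, 2 or 8, and that of COX8A without slide 3 and with 1 weight per group. With each array centred, the median was 0.01. The calls of COX5A (adjusted p = 0.562) and COX8A (0.357) ended with slide as a block. Those of HES1 (adjusted p = 0.436), COX5A (0.0926) and COX8A (0.189) ended without the 4 HS arrays that stood apart. The median log2 difference of all tested probes was -0.05.

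Immediate early and heat shock genes, which respond to tissue handling, rose in 1 and fell in 1 of 16 (adjusted over the list alone, 1 and 1), the heat shock gene HSPA6 at 0.94 ± 0.25 (adjusted p = 0.00792) and EGR3 at -1.01 ± 0.26 (adjusted p = 0.00679). JUN did not pass at 0.70 ± 0.35 (adjusted p = 0.129), and the list was not called (median 0.07, camera adjusted p = 0.531). Of 3 haemoglobin and red cell genes HBB rose (2.27 ± 0.70, adjusted p = 0.0200, 1 of 3, adjusted over the list alone, 1). HBA2, which has a near-identical copy and is uncertain, stood at 0.47 ± 0.60 (adjusted p = 0.568), with no call (median 0.47, camera adjusted p = 0.274) except in the fit of all probes (adjusted p = 0.0163). Without HS 10 alone the HBA2 difference, which is the haemoglobin median, was 0.11, and without the 4 HS arrays that median was -0.03. A dimmer HBA2 probe stood at 0.19 (adjusted p = 0.864). Muscle genes fell in 1 of 7 (adjusted over the list alone, 1), the troponin TNNC2 at -0.94 ± 0.18 (adjusted p = 0.000983). TNNC2 was over the floor in 1 HS and 11 Normal arrays. ACTA2 stood at 0.90 ± 0.36 (adjusted p = 0.0623), and there was no call (median 0.08, camera upward, adjusted p = 0.938, fry downward). None of 3 adipocyte genes passed (0 rose, 0 fell, also 0 when adjusted over the list alone). CIDEA stood at 0.34 ± 0.59 (adjusted p = 0.686), with 0.08 to 0.57 when each array was left out in turn, and there was no call (median -0.14, mean 0.02, camera downward, adjusted p = 0.981). The adipocyte median ran from -0.20 to 0.09 when each array was left out in turn. With slide as a block and within slides 2 to 5 the medians were 0.34 and 1.87, 1.46, -1.46 and -0.68 for haemoglobin genes, 0.10 and 0.34, 0.90, 0.21 and -1.02 for muscle genes, -0.06 and 0.26, -0.11, 0.08 and -0.43 for adipocyte genes, and 0.05 and 0.48, -0.13, 0.05 and -0.93 for immediate early and heat shock genes. Without the 4 HS arrays the muscle median was -0.32. Of the nerve and Schwann cell genes 5 were on the table and 0 were bright enough to test. The calls of NCSTN (adjusted p = 0.103), JAG2 (0.113) and HBB (0.142) ended with slide as a block. Those of NCSTN (adjusted p = 0.188), JAG2 (0.236), HBB (0.131), EGR3 (0.0949), HSPA6 (0.101) and RPL7 (0.178) ended without the 4 HS arrays that stood apart.

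Over the 36 lists tested, 26 were called by camera with the preset correlation, 21 upward and 5 downward, and fry called 23 of these in the same direction. With an estimated correlation camera called 0 (smallest adjusted p = 0.279, 2 lists at an unadjusted p under 0.05).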

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

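The test of the bright members of the epidermal list was chosen only after the result was seen, as were the bounds used to weigh slide as a block, itself a planned fit, and the list of general keratinocyte genes that the composition tests use. Of 168 measures checked among the 10 HS arrays (36 list scores, 131 genes and the median correlation with the Normal arrays), 9 had an array far from the others, with its gap to the nearest array past the critical value of Dixon's test for 10 samples. Chance flags about 1 in 20 groups, here 8.4. The adipocyte list score of HS 4 was 1.80, and the next highest was 0.38. The GBP4 value of HS 7 was 8.48 (nearest 6.88) and its IFNG value 5.95 (nearest 4.80). The SDC1 value of HS 10 was 6.51, below the nearest at 8.81. In HS 2 the KRT72 value was 6.60 (nearest 5.29) and the TNNC2 value 5.86 (nearest 4.67). In HS 3 the SOX10 value was 5.63 (nearest 4.95), the HSPA6 value 5.91, below the nearest at 6.76, and the DCD value 9.19 (nearest 4.49).

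In HS, 19 of 31 tested epidermal differentiation genes fell, and 5 of 12 antimicrobial genes rose and 1 fell, but both list calls are lost with an estimated correlation (adjusted p = 0.327 and 0.460), and that of the antimicrobial list also with slide as a block (0.286). A smaller amount of epidermis could lower every keratinocyte gene alike, and the general keratinocyte score differed by -0.996 (95% interval -2.48 to 0.49, 4 HS arrays below and 4 above all Normal arrays), or by -1.59 (-3.59 to 0.41) over members with a Normal mean over 8. Against that score the epidermal list was lower by -1.12 (-1.57 to -0.66, permutation p = 2e-05, below all Normal arrays in 9 of 10 HS arrays), or -0.91 (-1.48 to -0.33, permutation p = 0.00021, 7 of 10) over such bright members. The 2 lists thus moved apart. They were not matched in brightness, and the brightest general gene had a Normal mean of 10.4. A dimmer gene reaches background after a smaller fall, so over all 10 HS arrays this gap does not decide whether less epidermis was the whole cause. The general score was above all Normal arrays in 4 HS arrays, and the gap lay below all Normal arrays in 9 of 10. Some arrays with raised general genes thus hold the gap, which argues against less epidermis as its cause in those arrays. The antimicrobial list stood 2.31 above that score (1.57 to 3.05, permutation p = 2e-05, 7 of 10 above), but less epidermis predicts a fall and phagocytes make part of this list, so that difference decides nothing. A difference of disease state, of body site or of the layers sampled stays open and was not tested.

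Sweat gland markers were lower in HS by a mean score of -1.78 (95% interval -2.50 to -1.06). Less epithelium of every kind in the HS biopsies may account for it: against general keratinocyte genes the gland list differed by -0.79 (-1.96 to 0.39, permutation p = 0.155). That interval holds both 0 and the whole gland change, so over all 10 HS arrays less epithelium and a change of the glands themselves cannot be told apart. This reading of the interval was made stricter after the result was seen. The general keratinocyte score was above all Normal arrays in 4 HS arrays and below them in 4. The gland score was under the Normal mean in 10 of 10, which argues against less epithelium of every kind in the 4 above. Gland density also differs between body sites, and the site was not tested because the labels give none for HS.

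The count of 3435 called probes was weighed against chance, slide, position and earlier adjustment. Of 100 splits of the 21 arrays, the real one included, 1 gave as many calls. The highest other, whose group of 10 held 7 HS arrays, gave 1851. That argues against chance, but 100 splits cannot show a share under 1 in 100. The splits also treat the arrays as independent, which the labels do not state. With slide in the model 1857 probes passed, which argues against slide as the whole cause. Position on the slide and group cannot be told apart: the position slope within Normal arrays correlated at 0.294 with the difference across called probes, and 29 of 100 permuted positions gave as large a value (range -0.466 to 0.556). An adjustment for slide before deposit could inflate calls and also stays open, since 45.7% of probes had a slide p over 0.5 within Normal arrays, inside the permuted range of 33.3 to 66.5 (median 49.2), a reading also made stricter after the result was seen.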

How the results depend on the processing

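The alternatives with a floor of 5.5 or with 5 on at least 3 arrays, quantile normalization, centred arrays, 1 weight per group and without HS 5, 7, 9 and 10 were chosen after seeing the data. Unless said otherwise, the cause of a change was not tested. Among the counts and the 3 lists named by the series title, other filters, variance models, weights, scalings, fry, a random slide block (within-slide correlation 0.0444), and the mean of a gene's probes kept each count within 1.5 times and each list call. The antimicrobial median still moved from 0.63 to 0.36 with no filter, 0.96 with 5 on at least 3 arrays and 1.33 with array weights, in the first 2 cases over other members. Across those filters, models and scalings the count of called probes ran from 2819 (floor of 5.5) to 4239 (array weights), with 40.1% higher in HS after quantile normalization and 45.4% after centring, against 42.5%. What the arrays' background limits is the dim genes: only 382 of 639 list genes on the table could be tested.

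Slide as a fixed block takes HS 3, 5, 6, 7 and 8, on slides without a Normal array, out of the comparison of the groups. With slide as a fixed block, 1857 probes passed and the antimicrobial median was 0.20 (adjusted p = 0.286). On the slides with both groups alone, where fewer arrays enter, 1146 passed, 465 at least 2-fold, and that median was 0.20 (adjusted p = 0.310). Within slide 2, 0 passed in limma, also 0 at least 2-fold, with 1947 at an unadjusted p under 0.05. Within slide 3, 2574 passed at least 2-fold, and within slide 4, 644 passed. The lone HS array of slides 3 and 4 is assumed to vary like the Normal arrays there, although 90.6% of tested probes had the higher SD in HS, so these counts are no firm test. The type I interferon median within slide 5 was 0.29. Leaving out slide 2, 3 or 8 gave 2066, 1823 or 1674 probes, with 503 at least 2-fold without slide 8, and leaving out slide 4, 6 or 8 gave antimicrobial medians of 0.69, 0.59 and 0.25. Without HS 5, 7, 9 and 10, with fewer samples and the HS arrays least like Normal taken out, 1484 passed and 307 at least 2-fold. With an estimated correlation the medians of 0.63, 1.06 and 1.15 for the antimicrobial, type I and interferon-gamma lists lost their calls (adjusted p = 0.460, 0.279 and 0.279).

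Leaving out each array in turn gave 2839 to 4212 probes, 658 to 1053 at least 2-fold, and medians of 0.37 to 0.85, 0.90 to 1.27 and 0.95 to 1.32 for the antimicrobial, type I and interferon-gamma lists. The antimicrobial call was lost without HS 3, 4, 6 or 8 (0.59, 0.55, 0.41 and 0.37). The labels do not say that replicate numbers pair the samples, and the values do not settle it. Of 10 pairs, 6 deviated together with a correlation over 0.1 (-0.07 to 0.49), and 2 of 10 arrays correlated best with their own number. These values were not set against permuted numbers. With the replicate number as a block 3120 probes passed, 836 at least 2-fold.

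Slides 3, 4 and 5 hold 1 HS array each (HS 9, HS 2 and HS 1). A turn of sign there rests on 1 HS biopsy, so slide and biopsy cannot be told apart. Among called lists and genes, log2 differences or list medians turned in sign within single slides, and without HS 5, 7, 9 and 10 the JAK-STAT median (-0.01) and the melanocyte median (0.17) did too, neither list being called there. Those of S100A7A, MMP1 and CXCL13, over the floor in no Normal array, are taken against background and are no folds. Within slide 3 these were the antimicrobial list (-1.29), stress keratins (-2.43), cell cycle (-0.39), PI3 (-1.35), SPRR2F (-1.30), SERPINB3 (-1.79), CCNB2 (-0.40), COX5A (-0.042), S100A7 (-0.99), S100A7A (-0.18) and MMP1 (-0.11). Within slide 4 they were macrophage markers (-0.027), cell cycle (-0.50), extracellular matrix (-0.30), metalloproteinases (-0.069), endothelial markers (-0.19), melanocyte markers (0.085), MMP3 (-0.069), DSC1 (0.36), IFNAR2 (-0.14), CXCL8 (-0.022), FPR1 (-0.12), CD163 (-0.88), CD207 (0.44), CPA3 (-0.28), COL5A2 (-0.0042), PECAM1 (-0.048), SOX10 (0.17), TNNC2 (0.21), JAG2 (0.46), HBB (-0.57) and CXCL13 (-0.084). Within slide 5, with 1 array per group and no test, they were B cell markers (-0.021), stress keratins (-0.12), cell cycle (-0.24), melanocyte markers (0.11), CD79A (-0.038), DSC1 (0.23), CLDN1 (0.51), CXCL8 (-0.44), ZC3H12A (-0.97), SOCS3 (-1.13), CD79B (-0.0032), FPR1 (-0.016), FCER1A (1.26), CD207 (0.59), CCNA2 (-0.16), CCNB2 (-0.095), RPL37 (0.029), ELANE (0.54), IL1B (-0.23) and CXCL13 (-0.16).

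Among the named genes, slide as a fixed block ended 28 gene calls. On the slides with both groups alone that block ended 47 and brought 1. A random slide block, which keeps all 21 arrays in the comparison, ended 2, and 3363 of the 3435 called probes still passed. Leaving out HS 5, 7, 9 and 10 ended 32 and brought 4. Leaving out 1 array at a time ended 70 and brought 45, summed over the 21 fits, and leaving out 1 slide at a time ended 87 and brought 24, summed over 8 fits. The fits without slides 6 and 7 are those without HS 3 and HS 5, so they enter both sums. Alternatives fixed in advance but not run, because the scanner columns carry no sample name, were quantile normalization without background correction, normexp with offset 50, neqc with equal medians, neqc with offset 50, and the detection filters at 0.01 on at least 10 arrays and at 0.05 on at least 3.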

Other observations

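The 4 relations between list scores were chosen after the scores were seen, so their p-values are adjusted over all 630 pairs of list scores. Single HS arrays differed in which immune markers they held. Plasma cell scores were 0.13, 1.02, 0.89, 0.31, 3.47, 3.35, 2.76, 2.79, 3.19 and 0.30 in HS 1 to 10. HS 10 held the highest haemoglobin score of the 10 HS arrays, 4.31. Stress keratin scores ran from -2.00 in HS 10 to 4.49 in HS 6, and epidermal differentiation scores from -4.97 in HS 9 to 0.97 in HS 3.

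Across the 10 HS arrays, the type I interferon score correlated with the T cell score (Pearson r = 0.935, permutation p = 0.00018, adjusted 0.00704 over the 630 pairs; Spearman rho = 0.879, permutation p = 0.00142, adjusted 0.0255), and r was 0.827 without HS 3 and 7. With the monocyte and macrophage score it gave r = 0.805 (permutation p = 0.00504, adjusted 0.0357) and rho = 0.867 (permutation p = 0.00226, adjusted 0.0294), and r was 0.679 without HS 3 and 7. The interferon-gamma score and the T cell score gave r = 0.927 (permutation p = 0.00011, adjusted 0.00678) and rho = 0.794 (permutation p = 0.00887, adjusted 0.0558, which did not pass), and r was 0.840 without HS 3 and 7. The IL-1, TNF and NF-kB score and the neutrophil score gave r = 0.965 (permutation p = 1e-05, the smallest that the permutations can give, adjusted 0.00158) and rho = 0.939 (permutation p = 0.00023, adjusted 0.0178), and r was 0.931 without HS 3 and 10. The paired lists share 0 genes. Over all 630 pairs the median r was 0.03, with quartiles of -0.40 and 0.52, and 113 pairs passed by r, 69 of them with r above 0. The 4 relations ranked 9, 61, 12 and 4 by r in the order given. No slide holds more than 3 HS arrays, so none gives a value of its own, and no cause was tested.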
